A study of Mus musculus with 28 samples.

How the data were processed

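RNA from 28 mouse samples was measured on Illumina arrays. Per the labels, 3 samples were normal B cells from the spleen of BALB/c mice aged 90 days, 14 were tumors that followed adoptive transfer of premalignant B cells, and 11 were tumors that arose spontaneously. The tumors carry the strain label C.iMyc/IL-6 on the BALB/c background, a combination of a Myc gene inserted into the genome with an IL-6 transgene. The adoptive-transfer samples were oil granuloma tissue taken at 105 to 158 days, and the spontaneous samples were lymph node tissue taken at 40 to 162 days, so the tumor kind and the tissue coincide. Per the labels' protocols, frozen tissue was ground, total RNA was extracted with Trizol, and biotin-labelled cRNA was prepared with an Ambion MessageAmp kit. The labels do not say whether the samples came from separate animals, so the p-values measure only the spread between these samples.

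The authors deposited 2 tables. The first holds, per the file headers, a probe intensity and a detection score for each array. The deposited intensity is on a linear scale, without background subtraction or normalization between arrays. The deposited detection score runs from 0 to 1 with high values for bright probes, and 1 minus this score was used as the detection p. The second deposited table holds log2 values. In every column of these deposited log2 values the distribution was the same, with a median of 7.15, and each column ranked its probes as its own intensities did (lowest rank correlation 0.999996), so these values are quantile normalized intensities. The submitters' processing notes name Partek without a version or a role. The chip or slide of each sample is not named in the tables.

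The linear intensities of 45281 probes were processed anew in R 4.3.3 with version 1.17.8 of data.table for reading and limma 3.58.1 for the fits. Background was corrected with the normal-exponential model of neqc, with the negative control distribution inferred from the detection p, an offset of 16, quantile normalization over the 28 arrays and a log2 transform. The probe annotation listed 1 gene symbol for 34885 probes, several symbols for 18 probes and no listed gene for 10378 probes. Of the 19057 symbols, 78 were not found by gene ID in the RefSeq gene table, and no probe was renamed. Each gene was represented by its probe with the highest mean over all arrays. A gene was tested if this probe had a detection p under 0.05 on at least 3 arrays, the size of the smallest group, which left 11804 genes. Probes with several symbols were not used here. The 3838 probes without a listed gene that passed the same filter were fitted apart.

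A single limma model with a mean per group was fitted to all 28 arrays, with moderated variances from eBayes, and 3 contrasts were taken: adoptive-transfer tumors against normal B cells, spontaneous tumors against normal B cells, and adoptive-transfer against spontaneous tumors. Tests were two-sided. Adjusted p-values are Benjamini-Hochberg values over the 11804 genes within a contrast, and a gene was called at an adjusted p under 0.05. A second count took called genes with a log2 fold change of at least 1 in size. A further limma model fitted a slope on age in days over the 11 spontaneous tumors. Errors of fold changes are standard errors (SE) of the model. Where no array of a group had a detection p under 0.05 for a gene, the fold is given as a lower bound, computed with each array of that group set at no less than its own lowest detected signal.

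Before the data were examined, 29 gene lists were written from textbook knowledge, with the tests, the alternatives and the rule for named genes. Of these, 28 lists had enough measured members. The immunoglobulin constant list had a single measured member, Ighg1, and is not used as a list here. Members were matched to the probe table by symbol and, where that symbol names no current gene, by older symbols. This matching was corrected after the main results were seen, because Gpi1, Eno1 and Loxl2 had first been matched to other genes. With the correction the glycolysis list, called between the tumor kinds before it, was no longer called there. The lists cover mature B cell, MHC class II, plasma cell identity, ER stress and secretion, MYC target, IL-6 and STAT3, proliferation, G1 cyclins and p53 pathway, BCL2 family, NF-kB target, interferon response, glycolysis, hypoxia, proteasome, homing and adhesion, myeloma-associated and inflammatory cytokine genes, and markers of macrophage, neutrophil, T cell, NK and cytotoxic, dendritic cell, fibroblast and matrix, endothelium, erythroid, adipocyte, mesothelium and mast cell. Each list was tested with camera at its preset correlation of 0.01, adjusted over the 28 lists within a contrast, and again with an estimated correlation. Member counts are given over all genes tested and adjusted over the list alone. The rule for named genes took, in each comparison, the 6 highest and 6 lowest called genes, up to 3 called members of each list with the largest change (or 2 per direction), and always Myc, Il6, Il6ra, Il6st, Stat3 and Socs3. For Il6st, 2 probes had a detection p under 0.05 on 2 and 0 arrays, so this gene was not tested. After the main results were seen, 5 lists were added: exocrine pancreas, pancreatic islet, immediate early, Y-linked and inducible heat shock genes.

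The tests were checked on simulated data with 50 changed genes per fold size among 11804 genes. Each gene was drawn independently from a normal distribution with its SD in each group, so correlation between genes and shifts of whole arrays were absent. With so few changed genes, a call needed a lower unadjusted p than in the real comparisons with normal B cells. The shares below therefore do not carry over directly to the real data. Of genes changed 2-fold, 50% were recovered in the first comparison, 34% in the second and 76% in the third. Of genes changed 4-fold, the shares were 86%, 92% and 96%. False calls made up 0.82% of calls in the first comparison, 0% in the second and 4.97% in the third. For a change over the whole age range, 26% of 2-fold and 80% of 4-fold changes were recovered. The number of arrays limits the precision of every value.

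The alternatives fixed in advance were no background correction, an offset of 50, median scaling, cyclic loess, the authors' log2 values, no filter, a stricter filter (detection p under 0.01 on at least 11 arrays), the mean of a gene's probes, eBayes with trend and robust, array weights per group or per array, only the 2 groups of a comparison, the replicate number as a block, age or cell makeup as covariates, each array left out in turn, ranks of age, and camera with an estimated correlation. A chip block was not run, because the tables name no chip. Added after the data were seen were fits without the 2 arrays with the fewest detected probes, without the 7 arrays with a raised exocrine pancreas mean (more than 1 log2 unit above the highest normal array), without both sets, with the exocrine pancreas mean as a covariate, and with Eif2s3y as a covariate. Differences in list means between the tumor kinds were also taken without the first 2 arrays, alone and with the exocrine pancreas mean as a covariate. The lists were also tested between the tumor kinds without the 3 adoptive-transfer tumors whose endothelium mean lay under 0.5 log2 units above the highest normal array, and list means with the macrophage score or the 4 cell makeup scores as covariates. Overlap between the comparisons against normal B cells was set beside 100 simulated draws of unchanged groups that share the controls.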

Results

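Expression was profiled in 3 samples of normal splenic B cells, 14 plasma cell tumors grown after adoptive transfer of premalignant B cells, and 11 spontaneous plasma cell tumors. Between 15633 and 16866 probes were detected per array in normal B cells, 11544 to 16827 in adoptive-transfer tumors and 14472 to 16756 in spontaneous tumors. Pearson correlations between arrays across genes ranged from 0.990 to 0.991 within normal B cells, from 0.752 to 0.984 within adoptive-transfer tumors and from 0.881 to 0.971 within spontaneous tumors. The median SD of a gene within its group was 0.15 log2 units in normal B cells, 0.50 in adoptive-transfer tumors and 0.32 in spontaneous tumors. The first principal component held 35.4% of the variance and the second 13.5%. Adoptive-transfer tumors 1 and 5 had the fewest detected probes, with 11544 and 13669.

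The first comparison asked how tumors from transferred premalignant cells differed from normal B cells. Genes of the mature B cell were lower and genes of the secretory pathway, the cell cycle and connective tissue were higher in the tumors. Of these lists mature B cell kept its call with an estimated correlation, while ER stress and secretion and proliferation each had an adjusted p = 0.225 with an estimated correlation and fibroblast and matrix 0.352. Fcmr, the Fc receptor for IgM, fell by 8.27 ± 0.73 on the log2 scale (SE, 14 tumors and 3 normal samples), a 309-fold lower intensity. Sel1l, a scaffold of the endoplasmic reticulum degradation machinery, rose by 3.86 ± 0.27, or 14.6-fold. Cdkn1a, the cell cycle inhibitor p21, was detected in no normal sample and was at least 38.1-fold higher in the tumors.

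Of 11804 genes, 4311 passed the threshold in limma, 2343 higher and 1968 lower in adoptive-transfer tumors, and 3023 of them changed by at least 1 log2 unit (1710 higher, 1313 lower). With median scaling of the arrays 33.3% of called genes were higher, against 54.3% here. All 20 measured members of the mature B cell list fell, with a median log2 fold change of -4.80, and the list kept its call with an estimated correlation (adjusted p = 0.00254). Besides Fcmr, Fcer2a, the low-affinity IgE receptor CD23, fell by 6.56 ± 0.24 and Ltb, a lymphotoxin subunit, fell by 6.21 ± 0.40. All 10 MHC class II genes fell, with a median of -4.95, including H2-DMb2 (-6.87 ± 0.87), which edits peptide loading, and Ciita (-5.72 ± 0.51), the master regulator of class II transcription. For this list the adjusted p was 0.0546 with an estimated correlation. The homing and adhesion list fell (median -1.16, 7 members lower and 2 higher of 15, adjusted p = 0.00155, and adjusted p = 0.122 with an estimated correlation). Its lower members included Klf2, a transcription factor of resting lymphocytes (-5.98 ± 0.74), and the follicle-homing receptor Cxcr5 (-5.40 ± 0.29). Counts adjusted over the list alone were the same for these 3 lists.

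Of 37 ER stress and secretion genes, 24 rose and 0 fell in adoptive-transfer tumors (24 and 1 adjusted over the list alone), with a median log2 fold change of 1.37. The list's adjusted p was 4.2e-08, and its adjusted p was 0.225 with an estimated correlation. Examples were Sel1l, the oligosaccharyltransferase subunit Ddost (3.15 ± 0.28) and the signal peptidase subunit Spcs3 (3.14 ± 0.47). In the plasma cell identity list, 9 members rose and 3 fell of 17 (10 and 3 adjusted over the list alone), with a median of 1.29, and the list was not called (adjusted p = 0.234). Fkbp11, a folding factor abundant in secretory cells, rose by 3.76 ± 0.62, Derl3, a component of endoplasmic reticulum degradation, by 3.26 ± 0.37, and Sdc1, the plasma cell surface marker CD138, by 1.98 ± 0.41. Of 29 proteasome genes 19 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.81, an adjusted p of 0.000156, and an adjusted p of 0.284 with an estimated correlation. Psmd14, a deubiquitinase of the 19S lid, rose by 1.59 ± 0.36.

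Among 28 proliferation genes, 21 rose and 0 fell in adoptive-transfer tumors, with a median of 2.14, and among 33 MYC target genes 22 rose and 0 fell, with a median of 1.12; these counts were the same adjusted over the list alone. Both lists had an adjusted p of 0.225 with an estimated correlation. Cdk1, the mitotic kinase, rose by 3.21 ± 0.37 and Birc5, the mitotic protein survivin, by 3.37 ± 0.42. Srm, the spermidine synthase, rose by 2.79 ± 0.30 and Ccnd2, the G1 cyclin D2, by 2.52 ± 0.27. The G1 cyclins and p53 pathway list was not called (8 members up and 3 down of 19, 9 and 3 adjusted over the list alone, median 0.97, adjusted p = 0.0669, or 0.04997 without normal sample 1). Within the BCL2 family list, which was not called (5 up and 4 down of 14, 6 and 4 adjusted over the list alone, median 0.28, adjusted p = 0.729), the antiapoptotic gene Bcl2 fell by 3.53 ± 0.47 while the antiapoptotic gene Bcl2l1 rose by 2.58 ± 0.52 and the proapoptotic gene Bbc3 rose by 3.31 ± 0.30. The glycolysis list rose (7 up and 1 down of 13, the same adjusted over the list alone, median 0.92, adjusted p = 0.0305, and adjusted p = 0.122 with an estimated correlation), with pyruvate kinase Pkm 2.46 ± 0.27 higher. Without adoptive-transfer tumor 5 this list had an adjusted p of 0.0674, and over 47 alternatives its adjusted p lay between 0.0054 and 0.198.

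Of 15 NF-kB target genes, 11 fell and 1 rose in adoptive-transfer tumors (the same adjusted over the list alone), with a median of -1.90 and an adjusted p of 0.123 with an estimated correlation. The B cell activation marker Cd83 fell by 6.20 ± 0.43 and the costimulatory receptor Cd40 by 5.21 ± 0.53. Cd40 is also a member of the mature B cell list, and the members Nfkbia and Tnfaip3 are immediate early genes too. Immediate early genes, a list added after the results were seen, were high in the normal samples (list means 10.4 to 10.6 log2 units, against 6.24 to 9.36 in these tumors): 22 of 25 members fell, among them the early growth response factor Egr3, at least 77.7-fold lower, and the activation antigen Cd69 (-6.87 ± 0.73). Fos, an AP-1 subunit, fell by 5.40 ± 0.82, and Junb, another, fell by 3.35 ± 0.45.

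Markers of other cell types also differed. Of 22 fibroblast and matrix genes 17 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 3.07 (2.47 with the 19 members detected in no normal sample set at their lower bound) and an adjusted p of 0.352 with an estimated correlation. The proteoglycan Dcn was at least 86.3-fold higher and smooth muscle actin Acta2 at least 49.4-fold higher. Of 17 endothelium genes 10 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 1.78 (1.30 with 10 members at their bound) and an adjusted p of 0.583 with an estimated correlation. This call was also lost without background correction (median 0.65, adjusted p = 0.0551), and over 47 alternatives the median lay between 0.65 and 2.78. The member that fell, Pecam1, encodes an adhesion molecule carried by leukocytes too (-2.10). Egfl7, a vascular matrix factor, rose by 4.82 ± 0.62. The macrophage list was not called (7 up and 2 down of 24, the same adjusted over the list alone, median 0.39, adjusted p = 0.166), although Gpnmb, a glycoprotein of lipid-laden macrophages, was at least 40.2-fold higher. The genes with the highest fold changes further included Klra17 (7.28 ± 0.63), a member of the Ly49 receptor family, Rsph1 (6.80 ± 0.38), a radial spoke component, the complement inhibitor Serping1 (at least 51.0-fold higher), the acute phase gene Saa3 (6.09 ± 0.93) and Xist, the RNA of the inactive X chromosome (at least 62.0-fold higher).

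The other lists were not called in this comparison: IL-6 and STAT3 (6 up, 8 down of 23), interferon response (2 up, 2 down of 19), hypoxia (4 up, 1 down of 13), myeloma-associated (2 up, 2 down of 12), inflammatory cytokine (7 up, 4 down of 24), neutrophil (0 of 15 changed), T cell (1 up, 2 down of 15), NK and cytotoxic (0 up, 2 down of 8), dendritic cell (1 up, 1 down of 8), erythroid (0 up, 1 down of 7), adipocyte (0 of 7 changed), mesothelium (3 up, 0 down of 8) and mast cell (0 of 6 changed). Their adjusted p-values lay between 0.0766 and 0.986. Adjusted over the list alone, IL-6 and STAT3 had 6 up and 9 down, hypoxia 5 up and 2 down, inflammatory cytokine 8 up and 4 down, T cell 1 up and 1 down, NK and cytotoxic 0 up and 1 down, and the rest the same counts. The erythroid median was 0.26 while its test pointed down. Cell kind, tissue and sex-linked transcripts coincided with the groups: Xist was detected in 0 of 3 normal samples and 14 of 14 adoptive-transfer tumors, and the Y-linked gene Eif2s3y in 3 of 3 and 0 of 14. With Eif2s3y as a covariate 1950 genes passed the threshold. The median size of the 4311 differences went from 1.32 to 1.29 and the median SE from 0.30 to 0.46, and 4309 kept their sign. Eif2s3y hardly varied within normal samples (8.93 to 9.04) or adoptive-transfer tumors (4.40 to 4.82), so this adjustment rests mostly on the spontaneous tumors (4.34 to 8.58). The kept sizes and signs therefore do not separate these differences from the sex-linked signal. For the 8 lists here and the 8 in the second comparison that lost their call only with an estimated correlation, that adjusted p was the highest over 47 alternatives.

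**Figure D1:**
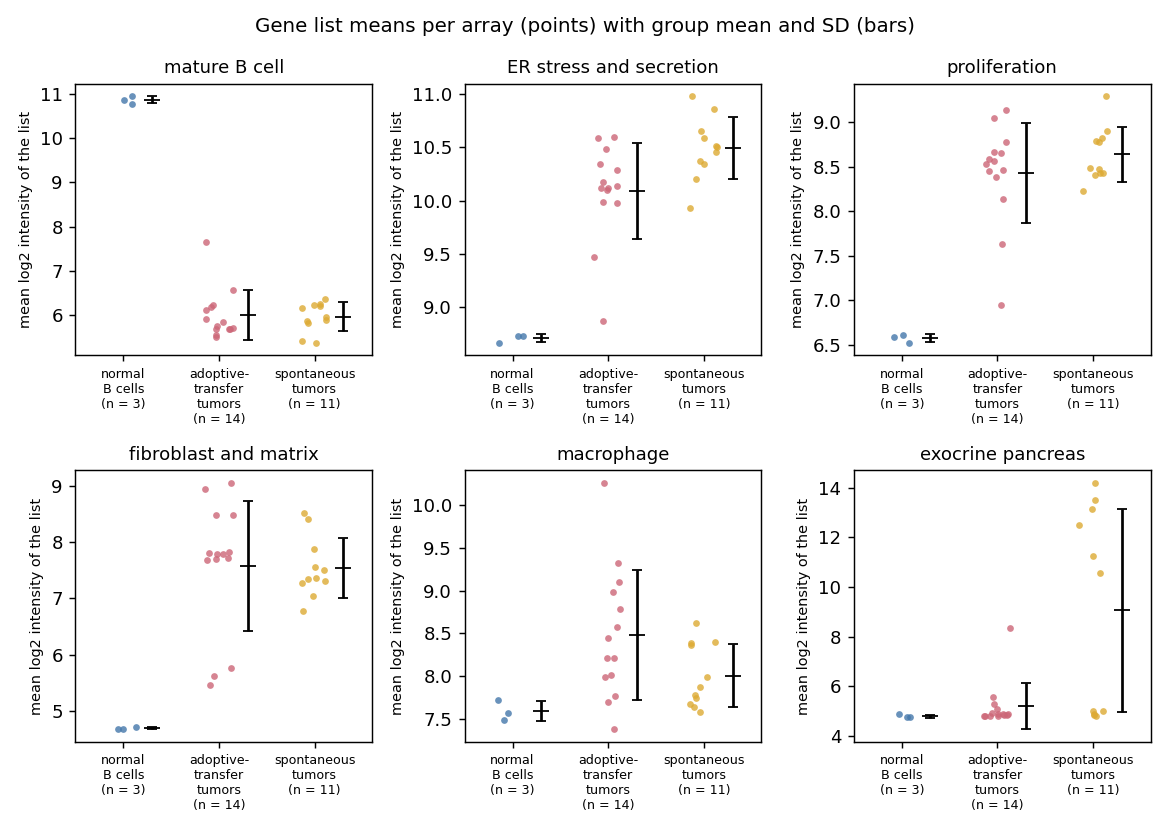
Mean log2 intensity of 6 gene lists in each array (points), with group mean and SD (bars), for 3 normal B cell samples, 14 adoptive-transfer tumors and 11 spontaneous tumors. Mature B cell means were 10.9 ± 0.085 (SD) in normal B cells against 6.00 ± 0.56 and 5.96 ± 0.33 in the tumors, and exocrine pancreas means, a list added after the results were seen, split the spontaneous tumors into 5 arrays at 4.81 to 5.00 and 6 arrays at 10.6 to 14.2.

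The second comparison set spontaneous tumors against the same normal B cells. The same kinds of genes stood out: mature B cell genes were lower, and secretory pathway, cell cycle, connective tissue and vessel genes were higher. Of these lists mature B cell kept its call, while ER stress and secretion and proliferation each had an adjusted p = 0.186 with an estimated correlation, and fibroblast and matrix and endothelium each 0.351. Fcmr fell by 8.49 ± 0.75 on the log2 scale (SE, 11 tumors and 3 normal samples), or 359-fold. Derl3 rose by 4.39 ± 0.38, or 21.0-fold, and Sdc1 by 3.02 ± 0.42, or 8.10-fold. Cdkn1a was at least 22.4-fold higher.

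In limma 4301 genes passed the threshold, 2185 higher and 2116 lower in spontaneous tumors, and 3035 of them changed by at least 1 log2 unit (1637 higher, 1398 lower). With median scaling 32.2% of called genes were higher, against 50.8% here. All 20 mature B cell genes fell (median -4.91), and this list kept its call with an estimated correlation (adjusted p = 0.00329). Blk, a Src family kinase of B cells, fell by 6.35 ± 0.51 and Fcer2a by 6.51 ± 0.24. All 10 MHC class II genes fell (median -5.17), with an adjusted p of 0.0643 with an estimated correlation. H2-Oa, which restrains peptide exchange, fell by 6.58 ± 0.44. The homing and adhesion list fell (6 members lower and 3 higher of 15, median -0.79, adjusted p = 0.00922, and adjusted p = 0.186 with an estimated correlation), with Klf2 at -6.85 ± 0.76 and the selectin ligand Selplg 1.71 ± 0.38 higher. Its adjusted p was 0.175 under the stricter filter and lay between 0.00313 and 0.186 over 47 alternatives. Counts adjusted over the list alone were the same for these 3 lists.

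Of 37 ER stress and secretion genes, 28 rose and 0 fell in spontaneous tumors (28 and 1 adjusted over the list alone), with a median of 1.78 and an adjusted p of 0.186 with an estimated correlation. Sel1l was 18.4-fold higher, and Spcs3 rose by 3.89 ± 0.48 and Creld2, an endoplasmic reticulum stress gene, by 3.80 ± 0.38. The plasma cell identity list was called (9 up and 3 down of 17, 10 and 3 adjusted over the list alone, median 1.49, adjusted p = 0.0396), but its adjusted p was 0.481 with an estimated correlation. It was 0.0557 without spontaneous tumor 7 and lay between 0.00861 and 0.481 over 47 alternatives. Its 3 lower members were the chemokine receptor Cxcr4 (-2.67), the BAFF and APRIL receptor Tnfrsf13b (-1.78) and the TNF receptor Tnfrsf18 (-1.21). The exocrine pancreas mean was raised in 6 of these 11 tumors. Of 29 proteasome genes 18 rose and 0 fell, the same adjusted over the list alone, with a median of 0.76 and an adjusted p of 0.308 with an estimated correlation.

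Of 28 proliferation genes 21 rose and 0 fell (median 2.35, adjusted p = 0.186 with an estimated correlation), and of 33 MYC target genes 20 rose and 0 fell (median 1.01, adjusted p = 0.308 with an estimated correlation), with the same counts adjusted over the list alone. Cdk1 rose by 3.55 ± 0.38 and Srm by 3.07 ± 0.30. The G1 cyclins and p53 pathway list passed narrowly (10 up and 3 down of 19, 11 and 3 adjusted over the list alone, median 1.13, adjusted p = 0.0465, and adjusted p = 0.186 with an estimated correlation). It lost its call without normal sample 2 (adjusted p = 0.0524), adoptive-transfer tumor 1 (0.0524), 2 (0.0512) or 5 (0.0937), or spontaneous tumor 6 (0.0699) or 7 (0.0557), and over 47 alternatives its adjusted p lay between 0.0176 and 0.186. Bcl2 fell by 3.92 ± 0.48 and Bcl2l1 rose by 2.73 ± 0.53 within the BCL2 family list, which was not called (7 up and 4 down of 14, the same adjusted over the list alone, adjusted p = 0.706). Of 15 NF-kB target genes 11 fell and 0 rose (the same adjusted over the list alone, median -1.85, adjusted p = 0.186 with an estimated correlation), with Cd40 at -5.68 ± 0.54, and 21 of 25 immediate early genes fell.

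Of 22 fibroblast and matrix genes 15 rose and 0 fell, the same adjusted over the list alone (median 2.93, or 2.39 with 19 members at their bound, adjusted p = 0.351 with an estimated correlation), and of 17 endothelium genes 13 rose and 1 fell, 14 and 1 adjusted over the list alone (median 2.11, or 1.93 with 10 members at their bound, adjusted p = 0.351 with an estimated correlation). Dcn was at least 69.4-fold higher, the matrix protein Sparc at least 38.6-fold, and the endothelial diaphragm gene Plvap rose by 5.33 ± 1.01. The pancreatic amylase gene Amy2a5 was at least 63.1-fold higher on average, above all normal samples in 9 of 11 tumors, with an adjusted p of 0.0150 in limma. This became 0.0567 without normal sample 2 and 0.0554 without normal sample 3, and over 18 other settings it lay between 0.000112 and 0.267, with log2 fold changes between 1.43 and 6.67. Without the arrays with a raised exocrine pancreas mean, 6 of these 11 tumors among them, the log2 fold change was 1.54 (adjusted p = 0.265).

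The lists not called here were IL-6 and STAT3 (5 up, 7 down of 23), interferon response (3 up, 2 down of 19), glycolysis (6 up, 1 down of 13), hypoxia (4 up, 1 down of 13), myeloma-associated (3 up, 2 down of 12), inflammatory cytokine (5 up, 3 down of 24), macrophage (7 up, 3 down of 24), neutrophil (0 of 15 changed), T cell (2 up, 2 down of 15), NK and cytotoxic (0 up, 2 down of 8), dendritic cell (0 up, 1 down of 8), erythroid (0 up, 1 down of 7), adipocyte (0 of 7 changed), mesothelium (2 up, 0 down of 8) and mast cell (1 up, 0 down of 6), with adjusted p-values between 0.0939 and 0.998. Adjusted over the list alone, IL-6 and STAT3 had 6 up and 9 down, interferon response 1 up and 1 down, glycolysis 7 up and 1 down, hypoxia 5 up and 2 down, mast cell 0 changed, and the rest the same counts. Test and median differed in sign for interferon response (median 0.052), dendritic cell (0.067) and erythroid (0.023), and the neutrophil mean was negative beside a median of 0.35.

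Both tumor kinds shared much of their difference from normal B cells. There were 1814 genes higher in both and 1769 lower in both, against 434 and 353 for independent lists, and 0 genes were called in opposite directions. Simulated unchanged groups that shared the 3 controls, with each gene drawn independently, had a mean of 0.07 shared calls. A low number was given in advance there, because no gene changed in the simulations. The log2 fold changes of the 2 comparisons had a correlation of 0.944 across genes, which are not independent replicates, against 0.326 in the simulations (0.291 to 0.363), and a covariance of 1.41 against 0.0134, a difference of 1.40. The 3 controls are too few to split, so the overlap could not be tested with separate controls for each tumor kind. Of the 3583 shared genes, 3481 had no called difference between the tumor kinds. Of 728 genes called only in adoptive-transfer tumors 70 differed between the kinds in the direct test, and of 718 called only in spontaneous tumors 85 did.

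**Figure D2:**
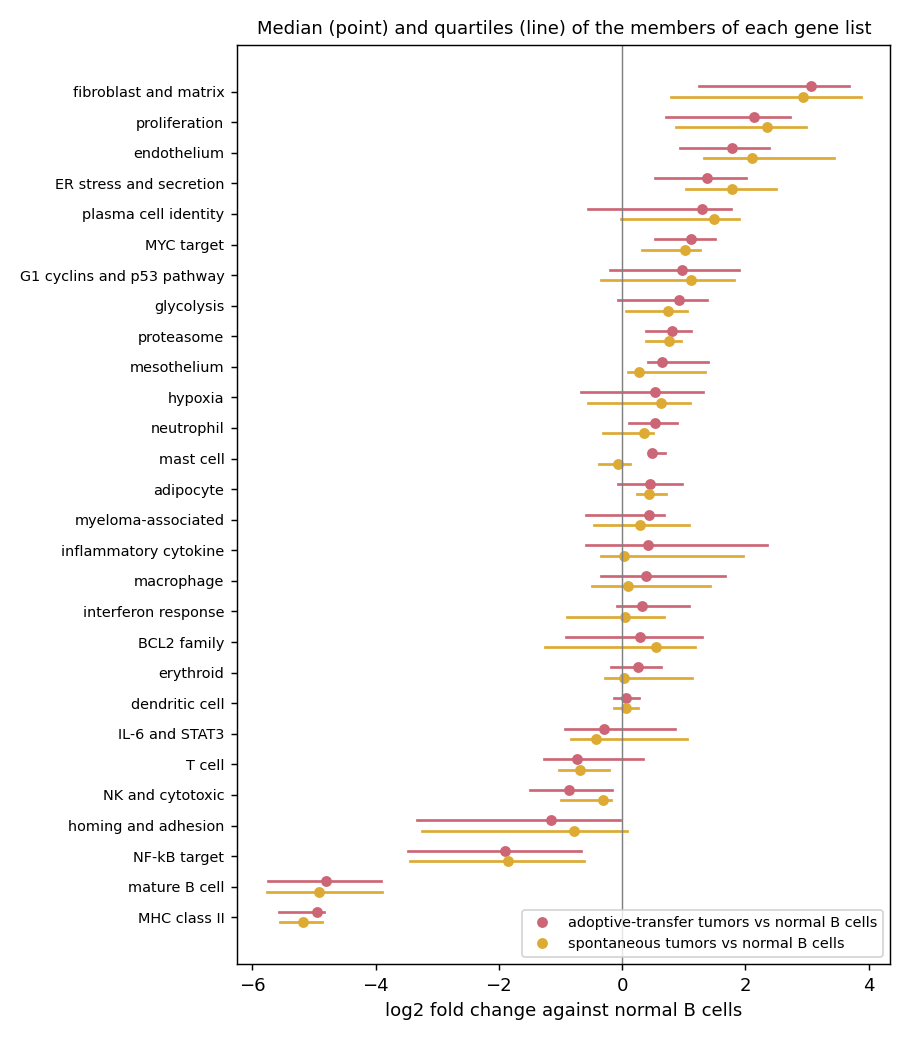
Median log2 fold change (points) and quartiles (lines) of the members of each of 28 gene lists, in adoptive-transfer and in spontaneous tumors, each against normal B cells. The mature B cell medians lie at -4.80 and -4.91 and the fibroblast and matrix medians at 3.07 and 2.93.

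The series title names IL-6, and the strain label of the tumors names Myc and IL-6 transgenes, so these genes were read in every group. Myc values come from its brighter probe, and its other probe had a detection p under 0.05 on 0 arrays. Whether the probes for Myc and Il6 read the transgenes was not tested, so the values do not measure transgene expression. Myc had a mean log2 intensity of 8.07 ± 0.21 (SD) in normal B cells, 8.53 ± 1.08 in adoptive-transfer tumors and 9.32 ± 0.62 in spontaneous tumors. It lay above all normal samples in 11 of 14 adoptive-transfer and 11 of 11 spontaneous tumors, with log2 fold changes of 0.46 ± 0.53 (adjusted p = 0.545) and 1.25 ± 0.54 (adjusted p = 0.0704) in limma. Without adoptive-transfer tumor 1, where Myc was lowest (5.46), the first log2 fold change was 0.69 (adjusted p = 0.151) and the second adjusted p, which this tumor enters through the shared variance, was 0.00967. Without adoptive-transfer tumors 1 and 5 the first was 0.82 (adjusted p = 0.0374), and with the replicate number as a block it was -0.25 (adjusted p = 0.765). The second adjusted p was 0.0492 without spontaneous tumor 5. Over 18 other settings the adjusted p-values lay between 0.00359 and 0.955 and between 8.5e-06 and 0.333, and the log2 fold changes between -0.25 and 0.82 and between 0.77 and 1.68. The IL-6 receptor gene Il6ra was above all normal samples in 14 of 14 and 11 of 11 tumors, with log2 fold changes of 1.49 ± 0.51 (adjusted p = 0.0217) and 1.22 ± 0.52 (adjusted p = 0.0690). The first of these was lost without any single normal sample (adjusted p = 0.0827, 0.0839 and 0.0539), and the second had an adjusted p of 0.0129 without adoptive-transfer tumor 5. Over 18 other settings they lay between 9.2e-05 and 0.0770 and between 2.2e-05 and 0.194. The mouse gene Il6 was detected in 0 of 3 normal samples, 5 of 14 adoptive-transfer and 1 of 11 spontaneous tumors. Stat3 had log2 fold changes of -0.02 ± 0.32 and -0.15 ± 0.33, and Socs3, the feedback inhibitor of IL-6 signalling, 0.23 ± 0.59 and 0.08 ± 0.61, none of them called. The IL-6 and STAT3 list was not called: of 23 members 6 were higher and 8 lower in adoptive-transfer tumors (median -0.30, adjusted p = 0.360) and 5 higher and 7 lower in spontaneous tumors (median -0.42, adjusted p = 0.507). Its members with the largest falls were Fos (-5.40 and -5.93) and Junb (-3.35 and -3.59), which are immediate early genes too. Among the members that rose, Vegfa, the vascular growth factor, was at least 9.74-fold higher in adoptive-transfer and at least 11.5-fold higher in spontaneous tumors, and Timp1, a metalloproteinase inhibitor, rose by 4.29 ± 0.89 and 3.86 ± 0.91. Vegfa is also a member of the hypoxia list, and Timp1 of the fibroblast and matrix list, which rose in both tumor kinds.

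**Figure D3:**
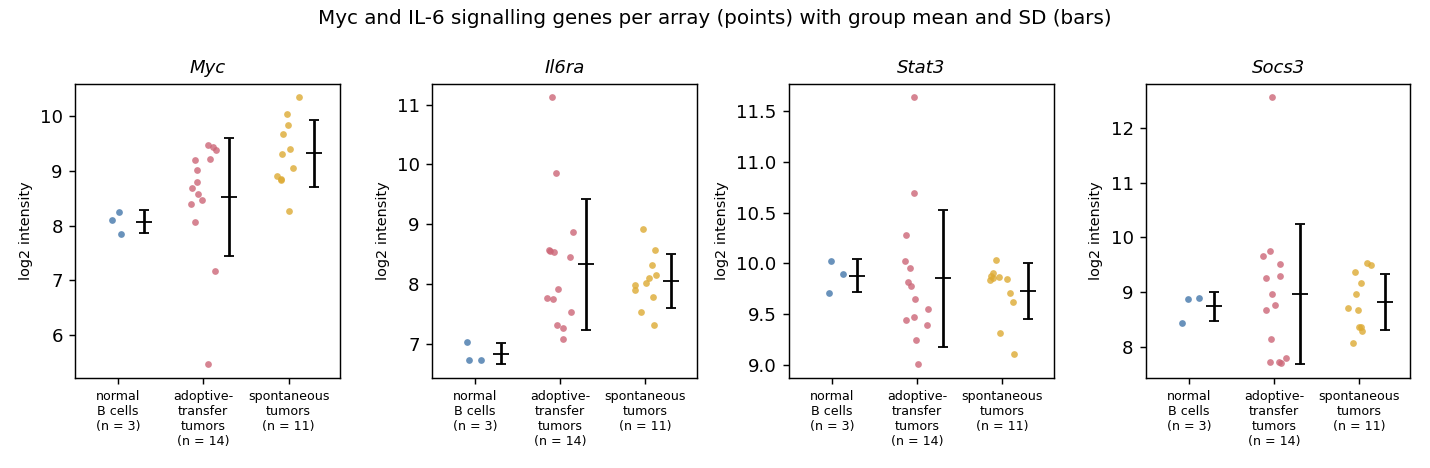
Log2 intensity of Myc, Il6ra, Stat3 and Socs3 in each array (points), with group mean and SD (bars), for 3 normal B cell samples, 14 adoptive-transfer tumors and 11 spontaneous tumors. Il6ra lies between 6.73 and 7.04 in normal B cells, between 7.08 and 11.1 in adoptive-transfer tumors and between 7.31 and 8.92 in spontaneous tumors.

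The third comparison set the tumor kinds against each other. Chil1, a chitinase-like protein of macrophages and epithelia, was 3.84 ± 0.45 log2 units higher in adoptive-transfer tumors (SE, 14 and 11 tumors), a 14.3-fold difference, and lay above every spontaneous tumor in 14 of 14. Saa3 was 10.7-fold higher and Vsig4, a complement receptor of tissue macrophages, 4.77-fold higher. Genes of pancreatic acinar cells were lower: Reg1 by a log2 fold change of -4.80 ± 1.12, the zymogen granule gene Gp2 by -4.57 ± 1.08 and Reg2 by -4.56 ± 1.07. Hyou1, a chaperone of the endoplasmic reticulum, fell by 1.14 ± 0.19.

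In limma 322 genes passed the threshold, 162 higher and 160 lower in adoptive-transfer tumors, and 108 of them differed by at least 1 log2 unit (28 higher, 80 lower). With median scaling 46 were higher and 94 lower. The trypsinogen genes Try10, Try4 and Try5 had log2 fold changes of -4.83, -4.67 and -4.67, with adjusted p-values of 0.0297, 0.0288 and 0.0317, and lay below every spontaneous tumor in 2, 6 and 1 of 14 adoptive-transfer tumors. Without spontaneous tumor 10 the adjusted p-values became 0.0643, 0.0616 and 0.0674, and the calls of Try10 and Try5 were also lost without spontaneous tumor 2, 4, 5, 8 or 11, and that of Try4 without 2, 4 or 8. Over 19 other settings the adjusted p of Try10 lay between 0.0122 and 0.982. Without the 7 arrays with a raised exocrine pancreas mean (6 spontaneous tumors and adoptive-transfer tumor 1), Reg1, Gp2 and Reg2 had log2 fold changes of -0.31, -0.12 and -0.22, and 67 genes passed the threshold. Over the 322 genes the median size of the difference went from 0.79 to 0.74 and the median SE from 0.19 to 0.21, and 312 kept their sign. The median size thus changed little, unlike the differences of the acinar genes, and 57 of the 322 genes were still called. Sizes were not compared gene by gene.

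The ER stress and secretion list fell (median -0.36, 1 of 37 genes lower and 0 higher, 4 and 1 adjusted over the list alone, adjusted p = 1.9e-08), and so did the plasma cell identity list (median -0.30, 2 of 17 lower and 0 higher, 3 and 0 adjusted over the list alone, adjusted p = 0.000827). Each had an adjusted p of 0.502 with an estimated correlation, and the exocrine pancreas mean was raised in 6 of the 11 spontaneous tumors. Without adoptive-transfer tumors 1 and 5, which had the lowest means of both lists, the medians were -0.25 (adjusted p = 1.1e-05) and -0.17 (adjusted p = 0.0370). Over 49 alternatives they lay between -0.52 and -0.25 and between -0.58 and -0.15. Derl3 fell by 1.13 ± 0.24 and Sdc1 by 1.04 ± 0.26. The Sdc1 call was lost without spontaneous tumor 4, 9 or 10 (adjusted p = 0.0543, 0.0516 and 0.0506), and over 20 other settings its adjusted p lay between 0.00641 and 0.776. The endothelium list fell (median -0.58, 0 of 17 members called by either adjustment including that adjusted over the list alone, adjusted p = 0.000141, and adjusted p = 0.719 with an estimated correlation), and the macrophage list rose (median 0.39, 2 of 24 higher, 3 adjusted over the list alone, adjusted p = 0.00157, and adjusted p = 0.944 with an estimated correlation), with the lysozyme gene Lyz1 1.14 ± 0.26 higher. Both calls were lost without adoptive-transfer tumors 5, 7 and 9, whose endothelium means of 5.35, 5.34 and 5.22 lay near those of normal B cells (4.99 to 5.16) and below the 5.94 to 8.43 of the other 11: the medians were then -0.17 (adjusted p = 0.0637) and 0.22 (adjusted p = 0.0659). In that fit ER stress and secretion (-0.31, adjusted p = 9.4e-07) and plasma cell identity (-0.32, adjusted p = 0.00372) kept their calls, and fibroblast and matrix was called as higher (0.48, adjusted p = 0.000496). The macrophage call was also lost without the arrays of low detection or raised pancreas signal (0.27, adjusted p = 0.0655) and with cell makeup covariates, which include this list (0.0042, adjusted p = 0.936). The proliferation list fell slightly (median -0.19, 0 of 28 members called, also adjusted over the list alone, adjusted p = 0.00398, and adjusted p = 0.944 with an estimated correlation). It had an adjusted p of 0.101 without adoptive-transfer tumors 5, 7 and 9, 0.129 without tumor 5 alone and 0.0725 without spontaneous tumor 3, and over 49 alternatives its adjusted p lay between 5.0e-05 and 0.949 and its median between -0.32 and 0.02. Psmb8, an immunoproteasome subunit, was 2.83-fold lower, and the uroplakin genes Upk3b and Upk1b were 2.31-fold and at least 1.59-fold higher, while their lists were not called.

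The other 23 lists were not called, with adjusted p-values between 0.148 and 0.931: MYC target (1 up of 33), BCL2 family (1 up, 1 down of 14), glycolysis (3 up of 13), proteasome (1 down of 29) and mesothelium (2 up, 1 down of 8) had called members, and mature B cell, MHC class II, IL-6 and STAT3, G1 cyclins and p53 pathway, NF-kB target, interferon response, hypoxia, homing and adhesion, myeloma-associated, inflammatory cytokine, neutrophil, T cell, NK and cytotoxic, dendritic cell, fibroblast and matrix, erythroid, adipocyte and mast cell had 0. The MYC target list (median 0.14) was called as higher in adoptive-transfer tumors without adoptive-transfer tumor 5 (0.22, adjusted p = 0.00438), without tumors 1 and 5 (0.24, adjusted p = 0.00105), with array weights per array (0.24, adjusted p = 0.000200) and with cell makeup covariates (0.25, adjusted p = 0.00135). Other lists were called under 1 or 2 alternatives: with weights per array mature B cell (-0.15), NF-kB target (-0.11), homing and adhesion (-0.18) and proteasome (0.12), with cell makeup covariates MHC class II (-0.37) and NF-kB target (-0.10), without tumors 1 and 5 proteasome (0.10), with the replicate block interferon response (0.59), without a filter glycolysis (0.17) and with the pancreas mean mesothelium (0.36). Adjusted over the list alone, proteasome had 1 up and 1 down, T cell 3 up, mast cell 2 up, adipocyte 1 down, and the rest the same counts. Test and median differed in sign for mature B cell, MHC class II, IL-6 and STAT3, homing and adhesion and adipocyte. The means of G1 cyclins and p53 pathway and of hypoxia were positive beside a negative median and test, and the proteasome mean was negative beside a positive median and test.

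This comparison depended on few arrays: 170 genes passed without spontaneous tumor 10, 197 without spontaneous tumor 8, 213 without spontaneous tumor 4 and 565 without adoptive-transfer tumor 5. Xist was detected in 14 of 14 adoptive-transfer and 6 of 11 spontaneous tumors, and Eif2s3y in 0 of 14 and 8 of 11. With Eif2s3y as a covariate 1 gene passed, Muc1, a membrane mucin, named after its values were seen (-2.45 ± 0.38, adjusted p = 0.00694). Age was tested within the 11 spontaneous tumors. In limma 0 of 11804 genes had a slope past the threshold, 1339 had an unadjusted p under 0.05 against 590.2 by chance, and the lowest adjusted p was 0.127. Spontaneous tumors 5, 6, 10 and 11, taken at 159 to 162 days, had Eif2s3y at 4.34 to 5.61. The others, taken at 40 to 130 days, had it at 8.27 to 8.58. Age and the sex-linked signal thus coincide in these tumors, and the slopes cannot tell them apart.

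**Figure D4:**
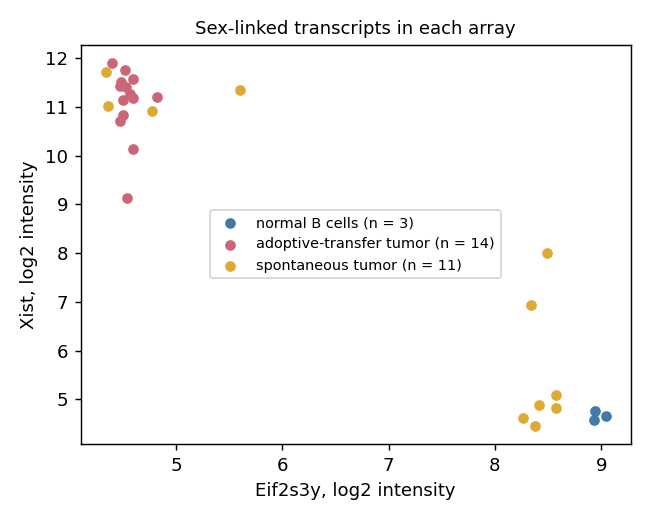
Log2 intensity of Xist (vertical axis) against Eif2s3y (horizontal axis) in each of 28 arrays. The 3 normal B cell samples lie at 8.93 to 9.04 for Eif2s3y and at 4.57 to 4.75 for Xist, and the 14 adoptive-transfer tumors at 4.40 to 4.82 and at 9.12 to 11.9.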

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

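Apart from the direct test between the tumor kinds, the splits of the arrays, the single arrays left out and the list medians with cell makeup covariates, the tests in this part were chosen after the main results were seen, and so were the lists of exocrine pancreas, islet, immediate early and heat shock genes. The results given here differed between the tumor kinds in the direct test or came from probes that the comparisons of named genes do not use, and the immediate early genes are a pattern of both tumor kinds against normal B cells.

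Between adoptive-transfer and spontaneous tumors 322 genes passed the threshold, and 1 of 100 splits of the same arrays into groups of the same sizes, the real one, gave as many, with 1 gene as the highest of the others. The splits count against a random grouping only if the arrays are independent samples, which the labels do not say. The tumor kinds differ in tissue by the labels and in their sex-linked and pancreas signal. A high count for the real split was therefore likely in advance, and the splits cannot tell tumor kind from these differences. For genes that also differed by at least 1 log2 unit the real split gave 108, again 1 of 100, with 1 as the highest other. With Eif2s3y as a covariate the median size of the 322 differences went from 0.79 to 0.73, the median SE from 0.19 to 0.28, and 321 kept their sign. The call ended for all but 1 gene with this wider error, and the sex-linked signal and the tumor kind remain partly confounded.

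Exocrine pancreas genes were higher in spontaneous tumors: the list mean was raised in 6 of 11 of them (10.6 to 14.2 log2 units) and in 1 of 14 adoptive-transfer tumors (8.33), against at most 4.87 in normal B cells, and the genes with the largest differences were Try10 (-4.83), Reg1 (-4.80), Try4 (-4.67), Try5 (-4.67), Gp2 (-4.57) and Reg2 (-4.56), adoptive-transfer minus spontaneous. In each raised spontaneous tumor at least 95.7% of the 23 list members lay over 1 log2 unit above their highest normal array, so the signal was not confined to a few list members. These tumors were chosen by the mean of the same list, which made raised members likely in advance. Expression of pancreas genes without the tissue is therefore not excluded by this count. Pancreas tissue in the samples may account for the signal: the islet list of 4 genes was raised in 3 of these 6 tumors and in 0 of the other 5 (test of pancreas tissue in the samples, value 3), and Cela2a reached 15.2 and Ins2 11.4 log2 units in spontaneous tumors. The labels name lymph node as the tissue, and no sort that would remove pancreas cells is named. Whether the tissue was taken along at dissection or invaded by tumor was not tested.

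The ER stress and secretion list (median -0.36) and the plasma cell identity list (median -0.30) were lower in adoptive-transfer than in spontaneous tumors, with Derl3 at -1.13, Sdc1 at -1.04 and Hyou1 at -1.14. Pancreas tissue in the spontaneous tumors, itself rich in secretory genes, is excluded as the whole cause, because with the exocrine list mean as a covariate the medians were -0.52 and -0.58 and the differences in list means went from -0.40 ± 0.16 to -0.55 ± 0.19 and from -0.35 ± 0.16 to -0.53 ± 0.20 (SE, 14 and 11 tumors). Part of the difference rests on adoptive-transfer tumors 1 and 5, which had the fewest detected probes and the lowest means (9.47 and 8.87 for ER stress and secretion, 7.44 and 7.32 for plasma cell identity): without them the medians were -0.25 and -0.17 and the differences in list means -0.25 ± 0.11 and -0.19 ± 0.11, or -0.37 ± 0.13 and -0.32 ± 0.14 with the exocrine list mean, so low detection in these tumors is argued against as the whole cause for ER stress and secretion and stays open for plasma cell identity. Tumor 5 also had the highest adoptive-transfer means of neutrophil (9.66, next 7.78), T cell (8.56, next 7.48) and mature B cell genes (7.65, next 6.57). Its proliferation mean was the lowest (6.94, next 7.63), and its fibroblast and matrix mean was low too (5.76, in a range of 5.46 to 9.05). Its content of other cells was not tested apart from its low detection. A lower share of tumor cells in the adoptive-transfer samples would raise the markers of every other cell type and stays open: the macrophage mean differed by 0.47 ± 0.25 and the endothelium mean by -0.60 ± 0.31 (SE), but the p of their gap of 1.08 (two-sided permutation test, p = 0.00198, 100000 resamples) is that of a pair chosen from its values and was 0.183 adjusted over the 55 pairs of 11 cell type lists (0.0108 for the widest pair, endothelium and mast cell, the latter a list of 6 genes with a mean of 5.24 in spontaneous tumors against 5.34 in normal B cells), and without adoptive-transfer tumors 5, 7 and 9, which had the lowest endothelium means (5.35, 5.34 and 5.22), the differences were -0.21 ± 0.23 for endothelium, -0.40 ± 0.16 for NK and cytotoxic, 0.57 ± 0.22 for fibroblast and matrix and 0.53 ± 0.24 for mast cell, and the gap was 0.52 (adjusted over the pairs, p = 0.0445). A change in macrophage content is argued against as the whole cause for ER stress and secretion and stays open for plasma cell identity, since with the macrophage score as a covariate the differences in list means were -0.36 ± 0.17 and -0.24 ± 0.17 (with 4 cell makeup scores the medians were -0.34, adjusted p = 4.2e-07, and -0.17, adjusted p = 0.0232), while the tissue site and origin of the tumors, which the labels give as differing between the groups, stay open and untested.

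Immediate early genes were higher in normal B cells than in both tumor kinds, with list mean differences of -3.47 ± 0.21 in adoptive-transfer and -3.69 ± 0.10 in spontaneous tumors (SE over 14 or 11 tumor and 3 normal arrays, list of 25 genes). Warm dissociation stress in the normal B cell samples would also raise inducible heat shock genes there. The 8 of these that were measured differed on average by 0.0972 ± 0.24 and 0.0388 ± 0.24, tumor minus normal. Their members went both ways: 1 was called higher and 2 lower in adoptive-transfer tumors, and 1 higher and 3 lower in spontaneous tumors. Bag3 rose (2.00 and 2.41), while Hspa4l (-1.74 and -1.71) and Dnajb1 (-0.75 and -0.86) fell. These values neither show nor exclude such stress. Stress during cell preparation, activation of the B cells and the loss of B cell identity in the tumors cannot be told apart, because all samples from spleen are normal B cells and the labels describe no dissociation step. No biological explanation was tested for this pattern. Adoptive-transfer tumor 5 had the highest tumor value, 9.36, with 7.63 as the next.

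Of the other lists that differed between the tumor kinds, proliferation had a median of -0.19, macrophage 0.39 and endothelium -0.58, adoptive-transfer minus spontaneous, and none of these 3 kept its call without adoptive-transfer tumors 5, 7 and 9 (-0.08, 0.22 and -0.17, adjusted p = 0.101, 0.0659 and 0.0637). Chil1 (3.84), Xist (3.47), Saa3 (3.42), Vsig4 (2.25), Ptgis (2.01) and Hal (1.57) were the genes with the largest positive differences. Further named genes that differed were Pkm (0.85), Tpi1 (0.74), Gapdh (0.55), Tfrc (0.74), Bad (0.41), Bcl2l2 (-0.80), Psmb8 (-1.5), Trem2 (1.5), Lyz1 (1.14), Upk3b (1.21), Krt18 (-1.02) and Upk1b, detected in no spontaneous tumor, whose fitted 1.23 stands only as at least 1.59-fold. Leaving out a single array ended the call under 18 of the 28 fits for Hal, 19 for Tpi1, 22 for Krt18, 11 for Tfrc, 10 for Bad, 9 for Trem2 and 3 for Bcl2l2.

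Of 3838 probes without a listed gene, 1218 passed the threshold in adoptive-transfer tumors against normal B cells (384 higher, 834 lower), 1125 in spontaneous tumors (359 higher, 766 lower) and 72 between the tumor kinds (23 higher, 49 lower).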

How the results depend on the processing

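The fits without arrays of low detection or raised pancreas signal, and those with the pancreas mean or Eif2s3y as a covariate, were chosen after the data were seen.

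Of the lists called against normal B cells, 1 of 11 in adoptive-transfer and 1 of 12 in spontaneous tumors, the mature B cell list in both, passed under every alternative run, as did 0 of 5 between the tumor kinds. Of the named genes that were called, 59 of 81, 65 of 80 and 0 of 27 did. With an estimated correlation 1, 1 and 0 lists passed. Between the tumor kinds 9 lists passed with array weights per array and 3 without both sets of doubted arrays. Signal over background limits genes near the detection limit, whose folds depend on the background correction. The chip block was not run, because no chip is named.

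For adoptive-transfer tumors against normal B cells, 4311 genes became 6532 with array weights per group, 7215 with weights per array and 1950 with Eif2s3y. The genes changed by at least 1 log2 unit, 3023 as reported, became 1453 without background correction, 1594 in the authors' processed values and 1829 with Eif2s3y. For spontaneous tumors 4301 became 7072 and 7161 with these weights, and 3035 became 1468 without background correction and 1612 in the authors' values. The shared changes of both tumor kinds against normal B cells, 3583 genes, became 5741 and 6211 with the weights and 1897 with Eif2s3y. The weights per group were 4.04 in normal B cells, 0.60 in adoptive-transfer and 1.30 in spontaneous tumors, and those per array averaged 3.48, 0.83 and 1.25. The uncorrected values keep a background that shrinks log2 differences, and Eif2s3y raised the median SE of the adoptive-transfer genes from 0.30 to 0.46; for the weights the cause was not tested.

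Between the tumor kinds, 322 genes became 140 with median scaling, 894 with weights per array, 207 with only the 2 groups, 651 with cell makeup covariates, 707 without the 2 arrays with the fewest detected probes, 67 without the arrays with pancreas signal, 183 without both sets, 169 with the pancreas mean and 1 with Eif2s3y. The 108 genes with at least 1 log2 unit became 38 without background correction, 43 in the authors' values, 166 with weights per array, 169 with cell makeup covariates, 46 without the arrays with pancreas signal and 1 with Eif2s3y. The cause was not tested. Without the arrays with pancreas signal 312 of the 322 genes had the same sign, and with the pancreas mean 319 did. The median size of these differences was 0.79 as reported, 0.74 without the arrays and 0.81 with the pancreas mean. The median SE was 0.19, 0.21 and 0.22, so these calls were lost while the median difference kept about its size.

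The replicate numbers showed no clear pairing of samples: correlations of equally numbered samples after removal of group means lay between -0.0719 and -0.0569, between -0.0475 and 0.0140 and between -0.0799 and 0.216. The last range is that of adoptive-transfer with spontaneous tumors, where 3 of 11 pairs were over 0.1. Unequally numbered samples were not correlated for reference, so pairing is not excluded. With the replicate block 3927, 3942 and 172 genes passed in the 3 comparisons, of which 3517, 3554 and 120 were among those reported.

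Some directions reversed: Xist had -0.24 in adoptive-transfer tumors against normal B cells and -0.38 between the tumor kinds with Eif2s3y. Try10 had 0.020 without the arrays with pancreas signal and 0.031 without both sets, and Try5 had 0.085 and 0.10. Xist and Eif2s3y varied inversely over most arrays, although 3 spontaneous tumors had both detected. The raised arrays held the high values of both trypsinogen genes.

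Leaving out 1 array gave 3215 (normal sample 2) to 5009 (adoptive-transfer tumor 5) genes for adoptive-transfer tumors, 3276 to 4744 (the same arrays) for spontaneous tumors, and 2710 to 4151 shared genes. With at least 1 log2 unit the ranges were 2602 to 3312 and 2667 to 3112. Between the tumor kinds 170 (spontaneous tumor 10), 197 (8) and 213 (4) to 565 (adoptive-transfer tumor 5) passed, and 60 (spontaneous tumor 10) to 132 (adoptive-transfer tumor 5) with at least 1 log2 unit. Called lists ranged from 10 to 12, 10 to 12 and 4 to 5, and age gave 0 genes in all 11 fits and with ranks.

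Median scaling moved the median of all genes by -0.18 in adoptive-transfer and -0.15 in spontaneous tumors, and the share of called genes that were higher from 54.3% to 33.3% and from 50.8% to 32.2%. The stricter filter moved the adoptive-transfer median by 0.10.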

Other observations

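No test in this part was chosen after the result was seen; the values of single genes and arrays were picked after looking at them.

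Ighg1, the constant region of IgG1 and the single immunoglobulin constant gene measured, ranged from 5.40 to 14.5 log2 units in spontaneous tumors, from 4.96 to 11.0 in adoptive-transfer tumors and from 6.43 to 6.79 in normal B cells. Jchain, the joining chain of polymeric immunoglobulins, ranged from 5.36 to 7.54 in spontaneous and from 4.45 to 6.86 in adoptive-transfer tumors and was detected in 11 of 11 and 12 of 14, against 0 of 3 normal samples. Actb lay between 12.7 and 14.9 in the tumors and between 13.8 and 14.5 in normal B cells.

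Adoptive-transfer tumor 5 was closest to a normal sample (r = 0.851 across genes, which are not independent replicates), while adoptive-transfer tumor 1 was closest to adoptive-transfer tumor 2 (r = 0.896). Adoptive-transfer tumors 11 to 13, all taken at 127 days, had their closest arrays among each other (r = 0.978 and 0.984), and so had tumors 3 and 4, taken at 105 days (r = 0.980). Xist and Eif2s3y were both detected in 3 spontaneous tumors.

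Splits of the same arrays into groups of the same sizes were also made for the comparisons with normal B cells. Splenic B cells were set against tumor tissue there, so a high count for the real split was near certain in advance. These splits therefore say little about the counts. In 1 of 100 splits, the real one, as many as 4311 genes passed for adoptive-transfer tumors, with 2552 as the highest other, in which adoptive-transfer tumors 1 and 5 stood with 1 normal sample as controls. With at least 1 log2 unit it was again 1 of 100, with 3023 against 1574. For spontaneous tumors it was 1 of 100 with 4301 against 88, and with at least 1 log2 unit 1 of 100 with 3035 against 84. For the 3583 shared genes it was 1 of 100 draws of 3 arrays as controls, with 847 as the highest other. The median of the other splits was 0 genes in each of the 3 comparisons, and the split with 2552 genes points to adoptive-transfer tumors 1 and 5 standing apart from the rest of their group.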
